A study of Mus musculus with 4 samples.

How the data were processed

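DNA methylation was measured by whole-genome bisulfite sequencing of CA1 hippocampal tissue in 4 mouse libraries, 2 labelled Tet2+f_Camk2aCre and 2 labelled Tet2+f. Per the labels' protocols, DNA was purified on columns, converted and made into libraries with the Swift Accel-NGS Methyl-Seq kit, and sequenced on a HiSeq X with paired reads of 150 bp at a stated 500000000 reads per sample. Bisulfite treatment does not separate 5-methylcytosine from 5-hydroxymethylcytosine, the product of TET enzymes, so a methylation level is the sum of both. A shift between these forms leaves the level as it was.

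Per the submitters' processing notes, the genome build was mm10 and the tools were FastQC 0.11.5, Trim Galore 0.4.5, Bismark 0.19.0 and edgeR, with no version given for the last and no role for any of them. The values deposited by the authors are percent methylation per region and library. How the regions were drawn, how CpGs were averaged within a region and whether a coverage minimum was set are not given in the sources used here. The deposited table has no counts or coverage, so levels from thinly and deeply covered regions enter with equal weight, and exact levels of 0% and 100% can come from few reads.

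Libraries were assigned to groups by their titles, and each column was matched to a library by the same title. Of 849172 regions, 158 lacked a value in at least 1 library and were left out, which left 849014. The main test planned before the data were examined was for counts of methylated and unmethylated reads. Because the table holds percent values only, the test foreseen for that case was used: limma 3.58.1 in R 4.3.3 on log2((level + 0.01) / (1 - level + 0.01)), with the level as a share of 1, moderated variances and Benjamini-Hochberg adjustment at 0.05. This transform gives large values to small changes next to 0% and 100%. Single levels, such as library means, were compared by an exact two-sided permutation test over 6 arrangements of the 4 libraries.

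Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 corresponds to, and 96.8% of the regions whose deposited gene name is in that table lay at that gene's position. The strand of a gene was taken from the deposited table, which gave 21908 genes a strand. Gene body levels were the mean of all regions overlapping the gene, for 49601 genes. Promoter levels were the mean of all regions overlapping 2000 bp upstream to 500 bp downstream of the gene start, for 21898 genes. Regions were assigned whole, so a long region can reach far outside the promoter or gene it counts for. Regions were also averaged into 479283 tiles of 5000 bp by their start.

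Before the data were examined, 14 gene lists with 456 genes were fixed, and all of these genes were found in the gene table, 3 of them by an older symbol. Each list was tested with camera, with a preset correlation of 0.01. The rule for named genes was also fixed beforehand: Tet2, the features past the threshold or, with none, the 5 smallest p in each direction, skipping predicted genes unless fewer than 6 others remain, the list members past the threshold (at most 4 per list and direction), and Tet1, Tet3, Dnmt1, Dnmt3a, Bdnf, Arc, Npas4, Fos and Egr1. Applied here, the genes that a region overlaps were ordered with protein-coding genes first and then by symbol. A region was skipped where the first of them was a predicted gene. The rule left open a region that holds both predicted and other genes, and the region over Ccl21b, for which the deposited table names a predicted gene, was kept. Camk2a and the regions with large differences that the closing section names were chosen after their values were seen.

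The limma test was tested on simulated levels with the means of the real libraries and a spread modelled on their replicates. For this, 200 regions or 200 promoters at 20 to 40% were raised by a known number of points. Among 849014 regions it recovered 0% of changes of 10, 20, 30 or 40 points and 25% of changes of 60 points, and between 8 and 45 unchanged regions passed as well. Among 21898 promoters it recovered 0% of changes of 10 points, 87% of 20 points and 98.5% of 30 points, with 0 to 6 unchanged promoters passing. These shares hold for 200 changed features, and a lone changed promoter has to reach a smaller p. The noise was normal on the percent scale, with variances redrawn at random from the replicate spread of features at like levels. Unchanged regions passed in the simulation and none passed in the real libraries, so the shares are approximate.

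Other settings chosen before the data were examined were a replicate block, autosomes alone, a minimum difference of 10 points, an adjusted threshold of 0.01, tiles, centring of each library, leaving out each library, other list tests and another promoter width. Those that need read counts were not run.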

Results

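Whole-genome bisulfite sequencing was used to measure DNA methylation in the CA1 field of the mouse hippocampus at 117 days of age, in the C57B6/J strain. The 4 libraries fall into 2 groups of 2. One group is labelled Tet2+f_Camk2aCre, read here as Cre recombinase under the promoter of Camk2a, a gene of excitatory forebrain neurons. The series text speaks of tissue with a reduced dose of Tet2 in glutamatergic cells. A level measured in tissue averages over its cells, so a change confined to glutamatergic cells would appear smaller here. The other group, labelled Tet2+f, has no Cre in its label and serves as the control. Tet2 encodes a dioxygenase that oxidises 5-methylcytosine, so the design asks whether, and in which direction, methylation differs when its dose is reduced. No group is labelled with Cre but without Tet2+f. A difference between the groups therefore cannot separate reduced Tet2 from the Cre or its transgene. The deposited table gives a percent methylation for each of 849172 regions in each library, and 849014 regions had a value in all 4. Those regions had a median length of 2589 bp, with quartiles of 1688 and 3960 bp. The table holds no read counts, so the depth behind each level is unknown and no interval for counting error is given. The labels do not say whether the 2 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

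The Tet2 gene itself, on chromosome 3 from 133463677 to 133545136 on the minus strand (mm10), did not pass the test of the group difference. Its gene body averaged 70.1% ± 0.532 (SD, n = 2) in the control libraries and 71.0% ± 2.40 (SD, n = 2) in the Cre libraries, a difference of 0.873 percentage points (limma adjusted p = 0.999). Leaving out replicate 1 of the Cre group turned this difference to -0.821 points. Each region counted equally, and regions of 124 and 162 bp at the gene start differed by 16.3 and 14.0 points. They were at 33.2% and 30.8% in replicate 1 of the Cre group and at 0% and 1.40% in replicate 2. The other regions differed by -5.74 to 3.54 points. The Tet2 promoter was at 8.50% and 6.20% in the control libraries and at 18.2% and 5.68% in the Cre libraries, so the higher group mean came from 1 library. Whether part of Tet2 was deleted was not analysed here, because the table gives levels and no coverage.

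The genome-wide level did not differ between the groups by more than the spread between replicates. The mean over all regions was 75.7% and 76.1% in the control libraries and 76.0% and 75.8% in the Cre libraries. The difference between the group means was -0.00683 points (exact permutation test, two-sided, p = 1). With 2 libraries against 2 there are 6 arrangements, and the smallest p this test can give is 0.333. Leaving out 1 library at a time moved the difference between -0.180 points, without replicate 1 of the control group, and 0.167 points, without replicate 2 of the control group. Every pair of libraries was closely related across regions, with r between 0.979 and 0.984. These are correlations over regions, which are not independent replicates. The 2 control libraries correlated at 0.981, the 2 Cre libraries at 0.981, and libraries of different groups at 0.981 on average.

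**Figure D1:**
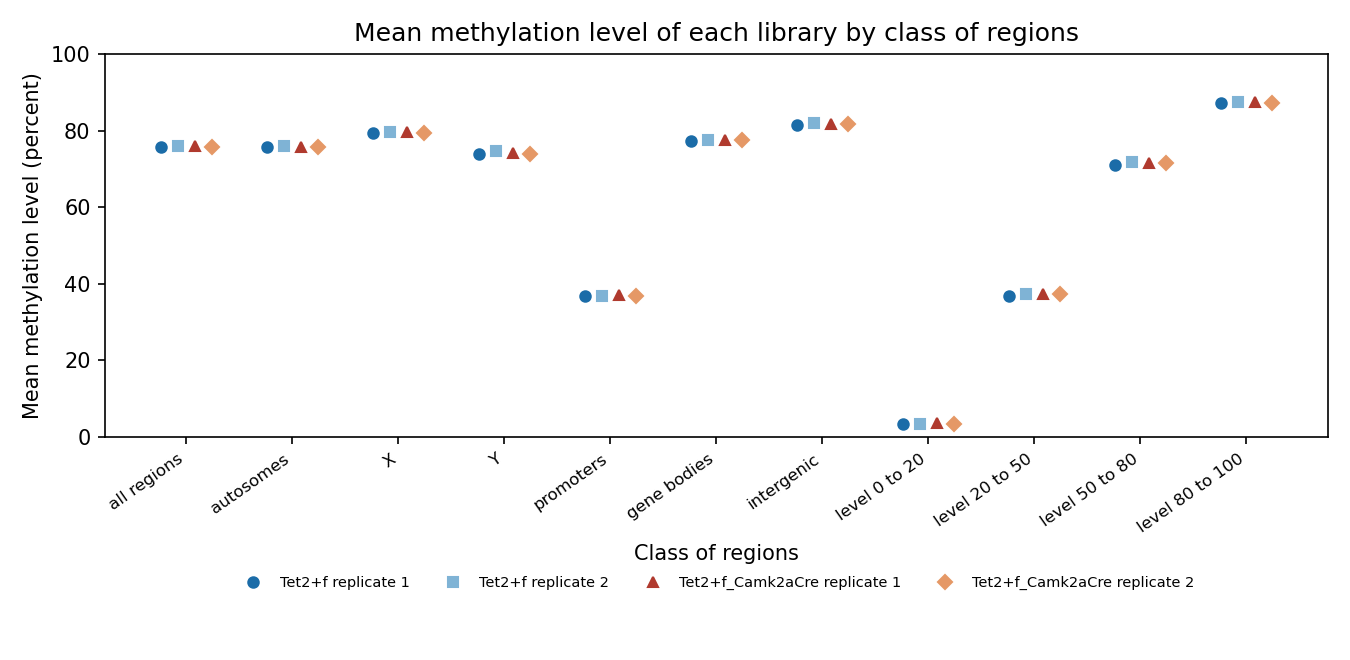
Mean methylation level (percent, vertical axis) of each of the 4 libraries in each class of regions (horizontal axis). Each point is 1 library. The 4 libraries lie close together in every class plotted, for example between 36.7% and 36.9% in promoters.

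Chromosome classes and genomic contexts also differed little between the groups. Autosomal regions differed by 0.000782 points, X-linked regions by -0.123 points and Y-linked regions by -0.265 points, and Y-linked regions had values in all 4 libraries. The Y-linked levels of the groups overlapped, at 73.8% and 74.6% in the control libraries and 74.1% and 73.8% in the Cre libraries. Regions in promoters, defined as 2000 bp upstream to 500 bp downstream of a gene start, averaged 36.8% ± 0.0921 (SD, n = 2) in the control group and 36.8% ± 0.136 (SD, n = 2) in the Cre group, a difference of 0.0727 points. That difference was -0.0238 points without replicate 1 of the Cre group. Gene bodies differed by 0.0338 points and intergenic regions by -0.0795 points. Grouped by their mean level over all 4 libraries, regions at 0 to 20% differed by 0.130 points, those at 20 to 50% by 0.263 points, those at 50 to 80% by 0.0675 points and those at 80 to 100% by -0.0668 points. The exact two-sided permutation p was 0.667 or 1 in each of these classes. At 20 to 50%, replicate 1 of the control group was at 36.8% and each other library at 37.3%, so that difference came from 1 library. At 50 to 80%, the Cre libraries, at 71.6% and 71.5%, lay between the control libraries, at 71.1% and 71.9%. Replicate 1 of the Cre group stood apart in its mean at regions of low methylation. Over regions under 10% it averaged 1.81%, against 1.60%, 1.64% and 1.62% in the others. Its median there, 0.556%, lay within those of the others, at 0.5%, 0.610% and 0.543%.

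No region passed the test of the group difference. With limma on logit-transformed levels and Benjamini-Hochberg adjustment, 0 of 849014 regions had an adjusted p under 0.05, and the smallest adjusted p was 0.937. At an unadjusted p under 0.05 there were 39068 regions, or 4.60% of those tested, of which 19130 were higher and 19938 lower in the Cre group. Over all regions 49.2% were higher in the Cre group. The same test on the percent scale passed 0 regions, as did limma with a trended and robust prior, and these gave 42071 and 40354 regions at an unadjusted p under 0.05. Averaging regions into 479283 tiles of 5000 bp passed 0 tiles (smallest adjusted p = 0.0798, 23779 at an unadjusted p under 0.05). Averaging over genes passed 0 of 49601 gene bodies (smallest adjusted p = 0.352, 2779 unadjusted) and 0 of 21898 promoters (smallest adjusted p = 0.230, 1126 unadjusted). On simulated levels with 200 of 849014 regions changed by 20 points, the region test recovered 0% of them after adjustment and 97.5% unadjusted, and 15 unchanged regions passed. The changed regions were drawn from those at 20 to 40%, and changes at other levels were not simulated. Unchanged regions passed in the simulation and none passed in the real libraries, so these shares are approximate. With 200 of 21898 promoters changed by 20 points the promoter test recovered 87%, and with a change of 10 points 0%.

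The regions with the smallest unadjusted p in each direction did not pass the adjusted threshold. Those higher in the Cre group lay in Kmt5a, a histone H4 lysine methyltransferase (chromosome 5, 124445445 to 124445567, 0% in both control libraries and 12.6% and 15.0% in the Cre libraries), in Hs3st4 (chromosome 7), 13 bp from Zfp362 (chromosome 4), between genes on chromosome 1 with Pard3b the nearest coding gene at 139852 bp, and in Rad18, a ubiquitin ligase of DNA damage tolerance (chromosome 6). Their differences ran from 8.88 points for the region between genes on chromosome 1 to 14.9 points at Zfp362. Those lower lay in Il1rapl2 (chromosome X, 138670169 to 138670858, 100% in both control libraries and 77.8% and 78.6% in the Cre libraries), in 2 regions far from any coding gene, on chromosome 12 (6516829 to 6520445, Klhl29 the nearest at 1141147 bp) and chromosome 16 (67934211 to 67934627, Cadm2 the nearest at 313294 bp), in a region of 164798 bp on chromosome 4 that spans Ccl21b and its copies, and in Kmt2c, a histone H3 lysine 4 methyltransferase (chromosome 5). Their differences ran from -10.5 points for the region on chromosome 16 to -21.8 points in Il1rapl2. The limma adjusted p was 0.937 for each of these 10 regions. In all but the region at Zfp362, the 2 libraries of one group were both at exactly 0% or 100%. The region over the Ccl21b copies is uncertain, since reads of near-identical copies cannot be assigned to one of them.

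The promoter of Camk2a, singled out after its values were seen, had the largest increase and the smallest p among the 21898 promoters. Camk2a encodes the alpha subunit of calcium/calmodulin-dependent protein kinase II, and it is the gene named beside Cre in the label of that group. The gene lies on chromosome 18 from 60925307 to 60988152 on the plus strand. Its promoter averaged 30.5% ± 0.113 (SD, n = 2) in the control group and 68.1% ± 2.13 (SD, n = 2) in the Cre group, a difference of 37.7 points (limma adjusted p = 0.230), which did not pass the threshold. Both Cre libraries lay above both control libraries. The difference was carried by 3 neighbouring regions between 60922197 and 60926634. The region from 60922197 to 60923683, upstream of the gene start, was at 40.8% and 40.4% in the control libraries and at 82.1% and 74.0% in the Cre libraries. The region from 60923684 to 60925300 was at 37.9% and 34.6% against 77.5% and 78.3%. The region from 60925347 to 60926634, inside the start of the gene, was at 12.95% and 16.1% against 49.3% and 47.7%. The neighbouring upstream region, from 60919512 to 60922168, was at 63.2% and 67.4% against 72.8% and 77.3%, and the next region into the gene, from 60926643 to 60928507, was at 65.0% and 66.6% against 68.6% and 48.4%. Over the whole gene body the groups averaged 60.2% ± 2.01 (SD, n = 2) and 62.4% ± 0.121 (SD, n = 2), a difference of 2.15 points (limma adjusted p = 0.982).

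**Figure D2:**
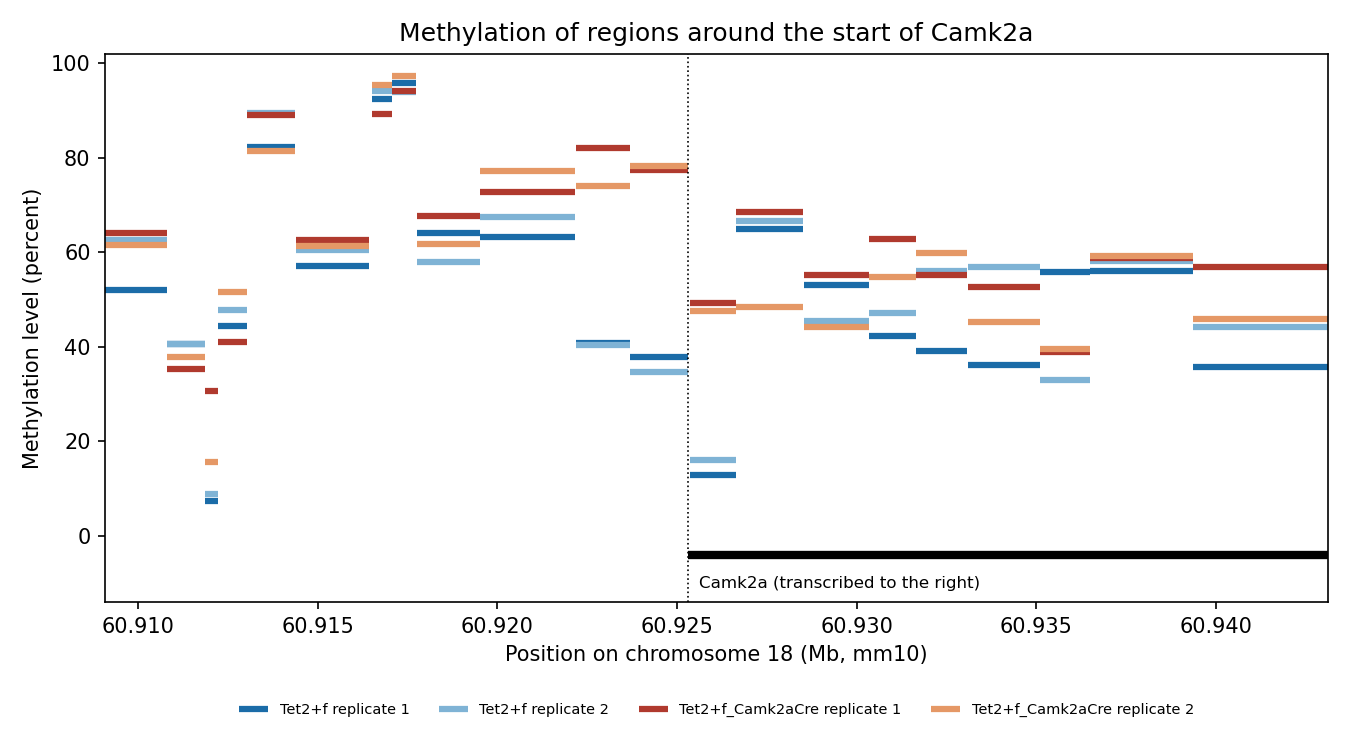
Methylation level (percent, vertical axis) of each deposited region (horizontal bars) in each of the 4 libraries along chromosome 18 (Mb, mm10) around the start of Camk2a, which is marked by the dotted line. In the 3 regions between 60922197 and 60926634 both Cre libraries lie above both control libraries, at 47.7% to 82.1% against 12.95% to 40.8%.

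None of the 9 genes of the methylation machinery and of neuronal activity named beforehand passed the threshold over gene bodies, which does not show that their levels were alike. The other dioxygenases of the family, Tet1 and Tet3, differed by 0.412 and -0.142 points. Dnmt1, the maintenance methyltransferase, was at 79.9% ± 0.195 (SD, n = 2) in the control group and 80.7% ± 0.131 (SD, n = 2) in the Cre group, and the de novo methyltransferase gene Dnmt3a differed by -0.267 points. Bdnf, which encodes a neurotrophin, differed by 0.112 points. Among immediate early genes, Arc was at 21.7% ± 3.22 (SD, n = 2) and 25.6% ± 0.00458 (SD, n = 2), and Egr1 at 26.4% ± 1.18 (SD, n = 2) and 29.7% ± 2.82 (SD, n = 2), while Npas4 and Fos differed by -0.108 and 0.494 points. The smallest limma adjusted p among these 9 genes was 0.945, for Arc. The direction of the difference turned for Tet3, Dnmt3a, Bdnf, Npas4 and Fos when 1 library was left out. The Arc difference of 3.96 points was 1.68 points without replicate 2 of the control group and 6.24 points without replicate 1 of that group. The Egr1 difference of 3.24 points was 1.24 points without replicate 1 of the Cre group and 5.23 points without replicate 2 of that group.

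Over gene bodies, none of the 14 gene lists fixed before the data were examined passed the test against the other genes, and no list had a member past the threshold, either over all genes or adjusted over the list alone. The smallest camera adjusted p was 0.567. Of all 49601 gene bodies, 50.1% were higher in the Cre group. In the CA1 pyramidal markers 17 of 22 measured members were higher in the Cre group and 5 lower, with a median difference of 0.432 points. Among genes of neuronal function, 34 of 54 glutamatergic synapse genes were higher, 31 of 49 memory and plasticity genes, 35 of 52 ion channel genes and 15 of 32 activity genes. In the methylation machinery 19 of 32 were higher, among imprinted genes 20 of 47 and among protocadherins 22 of 58. Among the markers of other cell types, 13 of 20 for dentate gyrus and CA3 were higher, 16 of 24 for interneurons, 12 of 18 for astrocytes, 9 of 20 for oligodendrocytes, 7 of 20 for microglia and 6 of 17 for endothelial cells. The camera adjusted p was 0.637 for activity genes, imprinted genes, protocadherins and endothelial markers, 0.746 for oligodendrocyte markers and 0.567 for the other 9 lists.

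Over promoters, 2 lists stood above the other promoters by camera with a preset correlation of 0.01, and neither call held with an estimated correlation. The preset form used the moderated statistics and the estimated form the logit levels, so they differ in more than the correlation. The glutamatergic synapse list had 30 of 51 measured promoters higher in the Cre group, with a median difference of 0.496 points (camera adjusted p = 0.0366, adjusted p = 0.768 with an estimated correlation). The CA1 pyramidal list had 16 of 21 higher, with a median difference of 0.319 points (camera adjusted p = 0.0366, adjusted p = 0.768 with an estimated correlation). Of all 21898 promoters, 50.8% were higher in the Cre group. Over all genes 0 members of either list passed, and adjusted over the list alone 1 member passed in each, Camk2a in both. Without Camk2a, a choice made after the data were seen, the camera adjusted p was 0.223 for both lists. The interneuron list had 7 of 22 promoters higher, with a median difference of -0.976 points (camera adjusted p = 0.185). The other 11 lists had camera adjusted p of at least 0.654.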

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

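The scales, priors, offsets, region filters, the minimum number of regions per promoter or gene, the lists without Camk2a, the length-weighted mean and the counts by size of difference were chosen after seeing the data. The count of 0 features past the threshold held under all 15 alternatives run, with a smallest adjusted p between 0.0731 and 0.954. These features were regions, except in the alternative that counted tiles. The share of regions higher in the Cre group, 49.2%, ranged from 47.0% to 50.5% over the libraries left out. With the replicate number as a block, 0 regions, 0 promoters and 0 gene bodies passed, and 0 gene lists passed over gene bodies or over promoters. Replicate differences of the 2 groups correlated at 0.00648 over regions, so the numbers were not taken to pair the libraries. The block leaves 1 residual degree of freedom. Without 1 library, the lone one is assumed to vary like the others.

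The genome-wide difference of -0.00683 points turned to 0.000782 points on autosomes and ranged from -0.180 to 0.167 points over the libraries left out. Likewise the promoter difference ranged from -0.0238 to 0.169 points and the X-linked difference from -0.283 to 0.0367 points. Gene body differences ranged from -0.821 to 2.57 points for Tet2, -0.559 to 0.276 for Tet3, -0.572 to 0.0381 for Dnmt3a, -0.285 to 0.508 for Bdnf, -1.03 to 0.818 for Npas4, -1.24 to 2.23 for Fos, 1.68 to 6.24 for Arc and 1.24 to 5.23 for Egr1. Apart from Tet2 and Camk2a, 0 of 114 values of named genes and regions under other settings passed the threshold. The cause was not tested.

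The Camk2a promoter was 36.2 to 39.2 points higher without any 1 library, with adjusted p from 0.518 to 0.9998. Among the 13500 promoters of 3 or more regions it passed (37.7 points, adjusted p = 0.0273), giving 1 promoter past the threshold. This minimum was chosen after the result was seen; Camk2a has 3 regions. With a minimum of 2 regions its adjusted p was 0.106, and minimums of 4 and 5, which leave Camk2a out, passed 0 promoters. Over its other alternatives the adjusted p ranged from 0.0927 to 0.9998.

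Among the list tests, camera compares a list with the other promoters, while fry tests it against no change. Over promoters alone 2 lists passed, 1 of them a cell type marker list, against 0 over gene bodies. That count of 2 fell to 0 with an estimated correlation, with fry, with the replicate block and without Camk2a, and to between 0 and 1 without 1 library. Regions with a difference of 20 points or more whose groups do not overlap numbered 311, and 676 to 1227 without 1 library. With 1 library in a group the groups overlap less often and that group's mean is a single level. These counts are therefore not comparable with 311. Coverage minimums of 20 and 4 reads, the coverage-weighted level, the planned likelihood ratio test, Fisher's exact test on summed counts and the offset of 1 read were not run, because the table gives no read counts.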

Other observations

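All tests here were chosen after the data were seen, and for the gene lists without Camk2a alone the outcome to look for was written down before its adjusted p was computed, while its other values were weighed afterwards. Large differences between the groups were set beside those between other pairings of the libraries. In 32.8% of regions the groups did not overlap, where chance gives 33.3%. There were 311 regions that also differed by 20 points or more, 178 higher and 133 lower in the Cre group, and the highest of the other splits gave 311, so that 2 of the 3 splits gave as many. That count of 311 was 738 and 1028 without replicates 1 and 2 of the control group and 676 and 1227 without replicates 1 and 2 of the Cre group. A group of 1 library meets the non-overlap rule more easily, so these counts are not comparable with 311. With 30 points or more and each pair of replicates within 10 points there were 17 regions, 12 higher and 5 lower, against 8 in the highest other split, so that 1 of the 3 splits gave as many. With 3 splits no share under 0.05 can be reached.

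Of those 17 regions, 12 were autosomal and 5 on chromosome X or Y. Of the 5 lower regions 3 were on X or Y and 1 was a region of 27834 bp over the predicted gene Gm3050. A further higher region spanned 46774 bp over Vmn1r135, of the large family of vomeronasal receptor genes. At the Camk2a promoter lay 3 of the 17. Other autosomal examples, picked by eye, were a region of 467 bp in Arid5b, a chromatin regulator (chromosome 10, 68225353 to 68225819, 33.3% and 42.2% in the control libraries, 91.7% and 97.1% in the Cre libraries), and one of 3242 bp in Abhd2 (chromosome 7, 79338200 to 79341441, 63.1% and 65.1% against 97.1% and 98.6%). A region of 125 bp in Apba1, a presynaptic adaptor gene, was at 11.9% and 7.52% against 48.2% and 49.5%. A region of 387 bp in 9130204K15Rik on chromosome 11 was lower, at 83.9% and 80% against 48.6% and 44.0%. There were 13 runs of 2 or more neighbouring regions with differences of at least 20 points, against 9 in each other split. Of the 13 runs, 10 were higher and 3 lower in the Cre group. A lower run, picked by eye, lay in the imprinted gene Grb10 (chromosome 11, 12025013 to 12025894, 65.6% and 73.9% against 48.5% and 48.4%). The list of imprinted genes passed neither over gene bodies nor over promoters (camera adjusted p = 0.637 and 0.654).

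The Camk2a promoter was 37.7 points higher in the Cre group, and higher in both Cre libraries. A general gain near that size at promoters of CA1 pyramidal genes is argued against by the 20 other measured members of that list. Their median difference was 0.294 points, with quartiles of -0.0257 and 1.59, which leaves a small general gain open. A gain near that size along the whole Camk2a gene is argued against by its 35 regions outside the promoter, with a median of 1.02 points and an upper quartile of 3.92. A candidate explanation is reads from Camk2a promoter copies in the Cre transgene that map to the native gene: Camk2a ranked 1 among 21898 promoters by increase, and it is the gene named beside Cre in the label. The promoter was noticed for its large difference, so this rank decides nothing and the explanation stays open. The transgenic line and the length of its promoter fragment are not given in the labels, no transgene sequence was analysed here, and an effect of reduced Tet2 on this promoter stays open and untested.

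The promoter lists of glutamatergic synapse and CA1 pyramidal genes both hold Camk2a. Without it neither passed, with a smaller adjusted p of 0.223, but that does not show that 1 gene carried the calls. The median difference went from 0.496 to 0.419 points for the glutamatergic list (quartiles without Camk2a -0.407 and 1.78) and from 0.319 to 0.294 points for the CA1 list (quartiles -0.0257 and 1.59). A median hardly depends on 1 member, and the mean went from 1.38 to 0.659 points and from 2.72 to 0.969 points. For the 2 lists in that order the unadjusted camera p was then 0.0180 and 0.0478, against 0.226 and 0.186 with an estimated correlation. The estimates were 0.0364 and 0.00969. The second lay under the preset 0.01, so the larger p for the CA1 list does not come from a larger correlation. With fry, which tests each list against no change and not against the other promoters, the unadjusted p was 0.0840 and 0.302. Whether Camk2a alone carried the calls stays open, and an effect of Tet2 on these promoters is open and untested.

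In replicate 1 of the Cre group 218 regions under 5% in the other 3 libraries were above 20%, against 22, 17 and 15 such regions in control replicate 1, control replicate 2 and Cre replicate 2. Their median length was 138 bp and 66.5% lay in promoters, against 150, 166 and 158 bp and 63.6%, 47.1% and 80% for the fewer such regions of the others in that order. An effect of the group is argued against by the 15 regions of the other Cre library. Incomplete conversion of this library as a whole is argued against by its mitochondrial level of 0.971%, below 1.49%, 1.35% and 1.61% in the others. That level averages 14 regions and cannot show incomplete conversion confined to short regions, which stays open. Thin coverage of short regions cannot be told apart from other sources, because the table gives no coverage. At short regions of intermediate level, each library was compared with the mean of the other 3, which also picked the regions. This library had 29 losses of over 20 points, against 58, 53 and 64 in the others, and 44 gains against 19, 19 and 17. Gains in this library raise the mean that the others are compared with, which adds losses to them. These counts therefore decide nothing about coverage.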
